A study of Homo sapiens with 58 samples.

How the data were processed

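The series holds single-cell bisulfite sequencing of HEK 293T, a human embryonic kidney line transformed with adenovirus DNA that also carries SV40 large T antigen. In this assay unmethylated cytosines are converted and read as thymine, so each read calls a cytosine methylated or unmethylated. The labels place 58 cells in 5 clones, namely P8_1 (12 cells), P8_2 (11), P8_3 (12), P9_1 (12) and P10_1 (11). What the parts P8, P9 and P10 of the clone names stand for is not given in the sources used here.

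Per the labels' protocols, single cells were sorted into 96-well plates, converted with a magnetic-bead bisulfite kit, copied with random primers in 5 rounds and amplified for 14 PCR cycles. The submitters' processing notes name Bismark 0.24.0 and the genome build hg38, with no role or order. Filters, removal of duplicate reads and the choice of cytosine context are not given in the sources used here. Per the file headers, the deposited tables give counts of methylated and unmethylated reads per cytosine position and strand. They also give the methylated fraction that the authors computed, which equalled methylated reads divided by all reads to within 1e-09 in all 58 files. The counts were used for every value below. Reads carry no molecular identifiers, so intervals cover counting error only.

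Cells held between 587235 and 10838313 covered positions, with a median of 1296315. Read counts summed over positions lay between 1024094 and 21791355. A read is counted at each position it covers, here and in every level below, so these sums are not numbers of sequencing reads. Between 52.7% and 76.2% of a cell's positions had 1 read. The methylation level of a cell is methylated reads divided by all reads on the autosomes, and a clone's value is the mean over its cells.

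Similarity of a pair of cells is Pearson's r of their methylation rates over autosomal 500-bp windows covered in both, without centring. Pairs shared between 8993 and 626266 windows. The contrast of a cell is its mean r with the other cells of its clone minus the mean over the other clones of its mean r with their cells. Each cell was also left out and assigned to the clone with the highest binomial likelihood of its reads, with clone rates shrunk to the mean of the 5 clones by a weight of 2 calls.

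Coverage of a chromosome is its share of a cell's covered positions, divided by the mean over the clones. Profiles over 5-Mb windows were divided by that mean too and then correlated between cells, unlike methylation rates, which were not centred. Chromosome coverage and clone-specific regions were also computed without 5 cells of uneven coverage, a choice made after the data were seen. Gene positions came from a RefSeq table of GRCh38.p14, the build the files use, with 19974 protein-coding genes. That table gives no strand, exons or sequence. Promoters were therefore replaced by the CpG-denser end of each gene with 1 kb on either side, by the positions covered in any cell. CpG islands were replaced by 500-bp windows with at least 40 such positions. Gene bodies were the interiors beyond 1 kb from both ends. A position was solo if no other lay within 35 bp. Exons, introns, repeats and sequence context were not analysed here.

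A region was clone-specific if 1 clone lay above or below all 4 others by at least 20 percentage points (100-kb windows with at least 10 positions per cell, gene bodies alike) or 30 points (gene ends, at least 3 positions). Cells with odd and even replicate numbers were taken separately, with at least 2 odd and 2 even cells of a clone for windows and gene bodies. Gene ends required 1 of each. The named genes are, per clone, the 3 gene ends and 3 gene bodies with the largest gap to the nearest other clone among those past the threshold with all cells and at least 0.5 of that gap in odd- and in even-numbered cells, plus members of the fixed lists past the threshold in both. For 16 fixed gene lists, the median gene-end level was set beside 10000 random lists of the same size matched on CpG density, as a description.

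The clone is the replicate. Contrasts were tested with a two-sided exact sign-flip permutation over the clones, which cannot go below p = 0.063 with 5 clones or 0.25 with the 3 P8 clones. The ID prefix was permuted over the clones in 10 ways, with a smallest one-sided p of 0.1. No test used cells as replicates. Whether the clones came from separate cultures is not stated beyond their names, and the plate or run of each clone is not given, so clone and batch cannot be told apart. The lists other than the panel genes, the rules, the tests of the comparisons and most alternatives were fixed before the data were examined, while several tests of explanations were chosen later.

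The steps were tested on simulated data with the real coverage, in which calls of 1 cell in a region were correlated. With 200 regions shifted by 50 points in 1 clone, odd- and even-numbered cells alike recovered 87.0% of 100-kb windows (14568 regions), 93.0% of gene bodies (5136) and 27.0% of gene ends (5351). Without any clone effect, 10 windows, 1 gene body and 58 gene ends passed in both sets of cells. The contrast without clone effects was 0.00217, between −0.00295 and 0.00744 by clone, over 4525424 windows. In the same simulation, centring on the mean of the 5 clones gave a contrast of 0.0616 and placed all 58 cells nearest to a cell of their own clone. That centring is therefore given only as an alternative, and its sign is not read as evidence of resemblance. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used. Alternatives covered window size, read and position minimums, thinning to 1 depth, centring, the classifier, thresholds and leaving out each clone.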

Results

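Methylation of single HEK 293T cells from 5 clones was measured to evaluate the performance of a lineage-tracing method based on DNA methylation, so the comparison the design implies is that of cells of the same clone with cells of different clones. The median number of covered positions per cell was 982999 in P8_1, 1126235 in P8_2, 1195674 in P8_3, 1634619 in P9_1 and 1955859 in P10_1. The deepest cell was A4 of P10_1, with 10838313 positions. Most single positions were covered by 1 read, so most values below rest on windows, genes or gene lists.

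HEK 293T cells carried intermediate methylation, with low gene ends and methylated gene bodies in every clone. The CpG methylation level was 60.8% ± 1.24 (SD, n = 5 clones), and single cells lay between 56.3% and 65.4%. By clone it was 62.3% ± 1.95 in P8_1, 61.5% ± 1.73 in P8_2, 59.8% ± 1.19 in P8_3, 61.1% ± 1.74 in P9_1 and 59.3% ± 3.01 in P10_1 (SD over cells). CpG-denser gene ends were at 15.7% ± 1.29 and CpG-dense windows at 30.9% ± 1.83 (SD, n = 5 clones). Gene bodies were at 73.8% ± 0.962, intergenic sequence at 65.5% ± 2.06 and solo positions at 66.4% ± 1.68. Gene ends lay −45.1 ± 1.67 points from the genome level and gene bodies 13.0 ± 0.481 points from it. Gene ends and dense windows were below the genome level in 58 of 58 cells, gene bodies and solo positions above it in 58 of 58, and intergenic sequence above it in 57 of 58. Each of the 5 differences had p = 0.063 by the two-sided exact sign-flip permutation test over 5 clones, the smallest the test can give. With at least 2 reads per position, the intergenic difference moved from 4.69 to 8.18 points and that of solo positions from 5.60 to 9.84 points.

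Median gene-end levels differed between the fixed gene lists, from 19.3% to 88.0%. The ± after a list median is the SD of the clone medians. The list median is not the mean of the clone medians and can lie outside them. Ends of 10042 protein-coding genes were measured in every clone, of which 4990 were under 20% and 1148 over 80%. Housekeeping genes had a median of 19.7% ± 2.74 (SD of clone medians, n = 5), with TBP, a subunit of the basal transcription machinery, at 6.67% ± 10.4 and LDHA, a lactate dehydrogenase, at 8.42% ± 4.41. Germline and cancer-testis genes had a median of 81.5% ± 5.95, at the 99.0th percentile of matched random lists. Other lists also lay high, with imprinted genes at the 99.96th, epithelial and mesenchymal genes at the 99.48th, tumour suppressor genes at the 99.25th and developmental transcription factors at the 97.8th. With 500 bp around gene ends these were the 91.71st, 99.05th, 71.86th and 94.46th, and germline genes were at the 99.455th. With 1 kb, protocadherin genes were at the 100th, pluripotency genes at the 98.36th and neuronal genes at the 97.5th. Most of the measured protocadherin genes share the same gene end, so their percentile cannot be read as that of separate genes. DNA methylation enzymes were at the 97.04th and kidney genes at the 95.6th, so the percentile does not set germline genes apart. Clone medians of epithelial and mesenchymal and of tumour suppressor genes were highest in P9_1, at 76.4% and 55.8%, against at most 50.7% and 26.5% in the others. Of the germline list's 13 measured members 7 were over 80%, among them DAZL, an RNA-binding protein of germ cells, at 96.2% ± 3.29 and DDX4, a germ cell helicase, at 91.7% ± 3.72. TDRD1, of the piRNA pathway, was at 4.68% ± 5.28 and MAEL, of the same pathway, at 6.17% ± 4.11. Of the pluripotency genes 3 were measured, with a median of 88.0% ± 4.28, SOX2 at 8.96% ± 6.70 and DPPA5 at 88.0% ± 5.16.

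HOX genes, which pattern the body axis, had a median of 22.2% ± 4.59, with 14 of 29 under 20% and 4 over 80%. HOXA4 was at 5.04% ± 4.66, HOXD12 at 93.6% ± 7.83 and HOXD10 at 96.7% ± 4.34. Developmental transcription factors had a median of 25.01% ± 3.68, with 12 of 33 under 20% and 6 over 80%. Their clone medians all lay above that value, from 26.0% in P10_1 to 35.5% in P8_1. GATA6, an endoderm factor, was at 2.55% ± 3.34 and PAX3, a neural crest factor, at 6.71% ± 6.23. PAX2, a kidney developmental factor, was at 93.3% ± 4.86 and SIX6, an eye factor, at 95.4% ± 3.41. Neuronal genes had a median of 30.9% ± 7.57, with GAD2, which makes GABA, at 19.8% ± 10.7 and TUBB3, a neuronal tubulin, at 90.5% ± 5.25. DNA methylation enzymes had a median of 29.8% ± 10.8, with the chromatin remodeller HELLS at 4.97% ± 6.89 and the demethylase TET1 at 6.52% ± 7.46. Zinc finger genes of chromosome 19 (101 measured) had a median of 23.3% ± 4.19 and histone genes one of 19.3% ± 14.4, from 1.57% in P8_2 to 40.01% in P8_1.

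Kidney genes had a median of 64.6% ± 13.1. The glucose transporter gene SLC5A2 was at 94.5% ± 8.15 and PODXL, a podocyte sialomucin, at 7.20% ± 4.71. Blood cell genes had a median of 74.1% ± 6.98, with clone medians from 56.1% in P9_1 to 75.6% in P10_1. FCER1G, an Fc receptor subunit, was at 94.8% ± 3.38. Olfactory receptor genes had a median of 61.9% ± 6.57, at the 8.77th percentile of matched random lists, and at the 69.96th with 500 bp around gene ends. Imprinted genes with a maternally methylated promoter had a median of 67.9% ± 10.3 over 9 measured members. PEG3 was at 71.1% ± 8.64, MEST at 89.0% ± 6.77 and PLAGL1 at 7.73% ± 5.61. The clustered protocadherin genes, cell adhesion genes that share long overlapping spans, had a median of 80.6% ± 12.8, and 21 of the 35 measured members shared 1 gene end at that value. Without strand the end chosen need not be the promoter. With 500 bp on either side, the medians were 28.8% for imprinted, 31.2% for protocadherin, 16.1% for kidney, 13.4% for tumour suppressor and 12.1% for HOX genes. They were then 16.7% for developmental factors, 15.0% for DNA methylation enzymes and 10.3% for zinc finger genes. With reads pooled per clone, the medians were 12.3% for housekeeping, 19.9% for neuronal, 12.2% for histone, 18.1% for tumour suppressor and 29.1% for epithelial and mesenchymal genes.

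The median gene-end levels of epithelial and mesenchymal genes and of tumour suppressor genes were higher in P9_1 than in the other clones, and P9_1 also had extra coverage of tumour genes. The median of epithelial and mesenchymal genes was 53.9% ± 12.9 (SD of clone medians, n = 5), with 76.4% in P9_1 and between 44.0% and 50.7% in the others. That of tumour suppressor genes was 29.2% ± 16.1, with 55.8% in P9_1 and between 14.9% and 26.5% in the others. P9_1 was the highest clone for 8 of 17 epithelial and mesenchymal genes and for 8 of 18 tumour suppressor genes, and the lowest for 2 of each. The lowest included SNAI1, a mesenchymal transcription factor, at 15.4% against at least 56.7%, and SLIT2, an axon guidance gene, at 1.49% against 1.66% to 68.9%, both chosen after their values were seen. In all 12 P9_1 cells, 83 genes of tumour sequencing panels held between 0.652% and 3.44% of the covered positions, against 0.278% to 0.591% in the 46 other cells. Their methylation level was 71.5% to 94.6% in P9_1 cells and 41.4% to 69.4% in the other cells. The panel list was written after hints of this pattern had been seen and shares 8 genes with the tumour suppressor list. VIM, the mesenchymal intermediate filament, was at 2.20% ± 2.08 over the clones, and RUNX3, a tumour suppressor, at 96.8% ± 2.36.

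**Figure D1:**
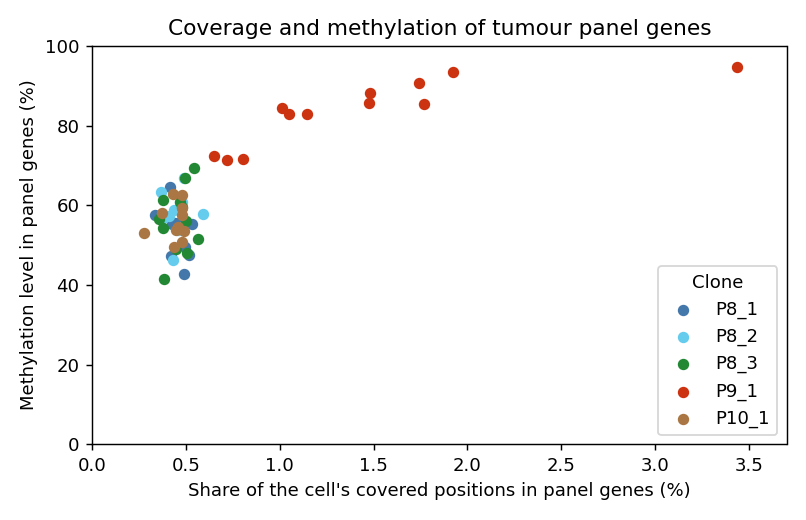
Share of a cell's covered positions in 83 tumour panel genes (x axis, percent) against the methylation level in those genes (y axis, percent), with each point a cell coloured by clone. The 12 P9_1 cells lie above all 46 other cells on both axes.

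Cells of the same clone resembled each other more than they resembled the mean of the other clones, in every clone, although P10_1 cells were more similar to P9_1 cells than to each other. Mean r was 0.549 (SD 0.042 over 308 pairs) within clones and 0.517 (SD 0.0386 over 1345 pairs) between clones. The contrast was 0.0319 ± 0.0165 (SD, n = 5 clones; exact sign-flip permutation p = 0.063, the smallest possible), and it was above 0 in 58 of 58 cells. P9_1 had the highest contrast, 0.0571, followed by P8_2 with 0.0402, P8_3 with 0.0225, P8_1 with 0.0217 and P10_1 with 0.0180. At single positions covered in both cells, the same call was made at 84.3% within and 81.5% between clones. Among the P8 clones alone the contrast was 0.0310 (3 of 3 clones above 0, exact permutation p = 0.25, the smallest possible). With 5-kb windows the contrast was 0.0193, with 4 of 5 clones above 0 (exact permutation p = 0.125). In windows with a mean rate of 20% to 80% it was 0.148.

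**Figure D2:**
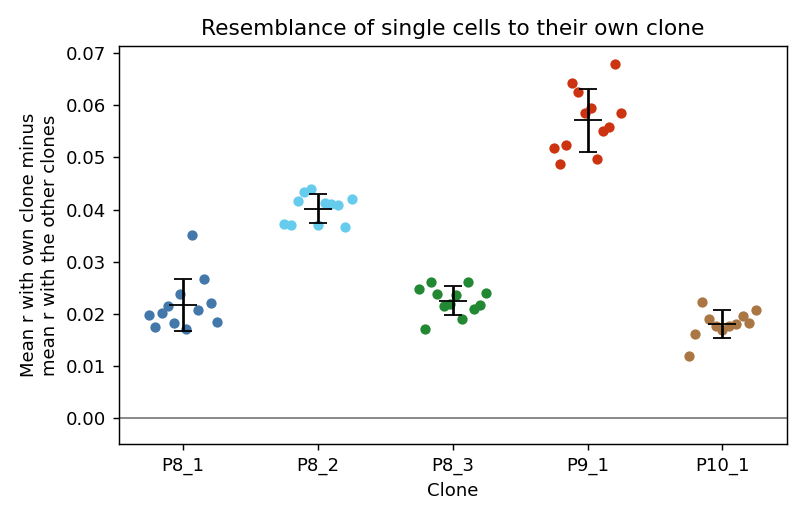
Mean r with the own clone minus mean r with the other clones (y axis) for each cell by clone (x axis), with the mean and SD over cells in black. All 58 cells lie above 0, with P9_1 highest at a mean of 0.0571.

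With all positions and without centring, P9_1 and P10_1 were the most similar pair of different clones, with a mean r of 0.549, above the 0.536 within P10_1. The pair had rank 2 of 10 at positions covered in 1 cell of a pair, where P8_2 and P9_1 came first (0.492 against 0.491). After thinning to 1 depth it had rank 1 or 2 over 5 draws without centring, and rank 3 with centring on the 3 other clones. With that centring and no thinning it had rank 1, with 0.220 against 0.165 for P8_1 and P8_2. None of the 11 P10_1 cells had its own clone as the nearest by mean r (0 of 11). P8_1 and P10_1 were the least similar, with 0.491. The P8 clones were not nearer to each other than the 7 other pairs were, with a difference of −0.0105 (one-sided exact permutation p = 0.7, 10 ways). Neighbouring rows of wells within a P8 clone had a mean r of 0.521 (rows A and B), 0.562 (C and D) and 0.538 (E and F). Neighbouring rows across clones had 0.503 (B and C) and 0.521 (D and E), so rows within a clone were higher by 0.0282 on average.

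Assignment by likelihood placed 27 of 58 cells in their own clone, against 4 of 58 in data simulated without clone effects. All 12 P9_1 cells and 10 of 11 P10_1 cells were placed correctly, but 0 of 12 P8_1 cells, 2 of 11 P8_2 cells and 3 of 12 P8_3 cells were. Of the misplaced cells 30 went to P10_1, whose pool held 27023582 autosomal positions, the most of the 5. Its cell A4 alone held 10838313 positions over all chromosomes. In the simulated data, 27 cells went to P10_1 and 31 to P9_1. With 100-bp windows 57 of 58 cells were placed correctly, with all cells thinned to 1 depth 52, and with 5-kb windows 16. With only the P8 clones as choices, 33 of 35 P8 cells were.

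The clones differed in coverage of whole chromosomes. Chromosome 4 had a relative coverage of 1.24 ± 0.364 in P8_1 and 1.22 ± 0.136 in P8_2 (SD over cells), and of 0.874, 0.871 and 0.787 in P8_3, P9_1 and P10_1. Chromosome 14 was at 0.695 ± 0.0678 in P8_3, 1.17 ± 0.13 in P9_1 and 1.19 ± 0.11 in P10_1. Chromosome 22 was at 0.765 ± 0.121 and chromosome 17 at 0.831 ± 0.0686 in P8_2. Coverage over the autosomes was uneven in P8_1 cells A2, A4 and B2 and in P10_1 cells A1 and A6, where the SD of coverage relative to the clone's median cell was over 3 times that of the median of all cells. Chromosome 22 was at 1.25 ± 0.465 in P8_1 with these cells and at 1.11 ± 0.171 without them, and chromosome 4 was then at 1.201 ± 0.109 in P8_1 and 0.845 ± 0.171 in P10_1. Coverage profiles over 5-Mb windows were more alike within than between clones, with a contrast of 0.133 ± 0.0153 (SD, n = 5 clones; exact permutation p = 0.063, the smallest possible), above 0 in 57 of 58 cells. These profiles were relative to the mean of the 5 clones, and no coverage contrast without clone effects was simulated. P9_1 and P10_1 had the highest profile correlation of the 10 pairs of clones, 0.0723.

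**Figure D3:**
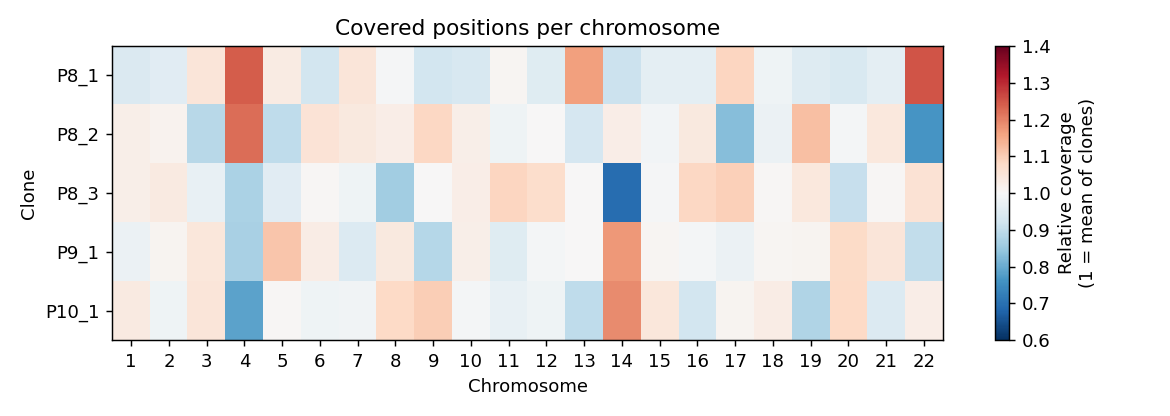
Relative coverage of each autosome (x axis) in each clone (y axis), with 1 as the mean of the clones and red above it. Chromosome 4 is high in P8_1 and P8_2 (1.24 and 1.22), and chromosome 14 is low in P8_3 (0.695).

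A group of gene bodies had higher methylation in P8_1 than in the 4 other clones. Of 41 gene bodies specific to a clone in the odd- and in the even-numbered cells, 32 belonged to P8_1, 30 of them higher there. MDGA2, a cell adhesion gene of neurons (chromosome 14, 46840624 to 47674604), was at 76.2% ± 8.99 in 11 P8_1 cells and between 23.8% and 32.9% in the other clones. ZNF804A, a zinc finger gene (chromosome 2, 184599530 to 184938491), was at 87.4% ± 4.51 in 6 P8_1 cells and at most 44.7% elsewhere. PKHD1, which encodes the ciliary protein fibrocystin (chromosome 6, 51616300 to 52086614), was at 69.8% ± 12.8 in 12 P8_1 cells and at most 27.8% elsewhere. ZNF701 of chromosome 19 was lower in P8_1, at 47.2% ± 19.3 in 4 cells against at least 76.7%. The same clone held 100 of 137 specific 100-kb windows, 96 of them higher, against 9.79 for P8_1 if odd- and even-numbered cells were independent. The largest gap was on chromosome 6 from 50100001 to 50200000, at 70.3% in P8_1 and at most 18.9% elsewhere. Without the cells of uneven coverage, left out after the data were seen, P8_1 had 63 windows and 27 gene bodies, of which 50 and 25 were among those above, where 65 of the 100 windows and 29 of the 32 gene bodies still met the minimum of cells. In data simulated without clone effects 10 windows and 1 gene body passed.

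In P8_2, the body of GNAS, an imprinted gene for a G-protein subunit (chromosome 20, 58840749 to 58910191), was at 30.6% ± 18.7 in 8 cells and at least 63.3% elsewhere. SMS, for spermine synthase, was at 86.5% ± 16.9 in 6 P8_2 cells and at most 57.1% elsewhere. GEMIN4, of the SMN complex, was at 100% in 4 P8_2 cells against at most 62.4%, with 0.199 times the coverage of the other clones. In P8_3, SYBU, for the kinesin adaptor syntabulin, was at 26.4% ± 22.3 in 5 cells and at least 57.9% elsewhere, with 0.562 times the coverage. ST8SIA1, for a ganglioside sialyltransferase, was at 39.4% ± 14.2 in 9 P8_3 cells against at least 60.8%. FBXW7, for a ubiquitin ligase subunit, was at 61.7% ± 28.4 in 7 P8_3 cells and at least 83.9% elsewhere, with 0.693 times the coverage. In P10_1, the body of the growth regulator MYC (chromosome 8, 127736435 to 127741950) was at 22.9% ± 22.4 in 7 cells and at least 49.0% elsewhere, with 1.03 times the coverage. HMGB1, a chromatin protein, was at 47.4% ± 26.5 in 8 P10_1 cells and at least 69.6% elsewhere, and MIEF1, of mitochondrial fission, at 48.7% ± 28.8 in 10 cells against at least 71.4%, with 3.61 times the coverage of the other clones. P8_3 and P10_1 had 0 gene bodies past the full threshold in odd- and in even-numbered cells.

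P9_1 bodies with higher methylation included panel genes at raised coverage. NTRK3, a neurotrophin receptor gene (chromosome 15, 87860752 to 88255738), was at 86.1% ± 13.0 in 12 cells and at most 34.6% elsewhere, with 6.87 times the coverage of the other clones. NRG1, for the growth factor neuregulin (chromosome 8, 31640246 to 32773045), was at 76.2% ± 13.8 and at most 29.2% elsewhere, with 2.65 times the coverage. ZNF584, which is not on the panel list, was at 82.5% ± 21.3 in 6 cells and at most 50.02% elsewhere, with 0.228 times the coverage. Without the 3902 bins of 10 kb covered over 3 times as much in 1 clone as in the others, a choice made after the data were seen, P9_1 kept 3 of its 5 gene bodies, 5 of its 11 windows and 21 of its 24 gene ends.

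**Figure D4:**
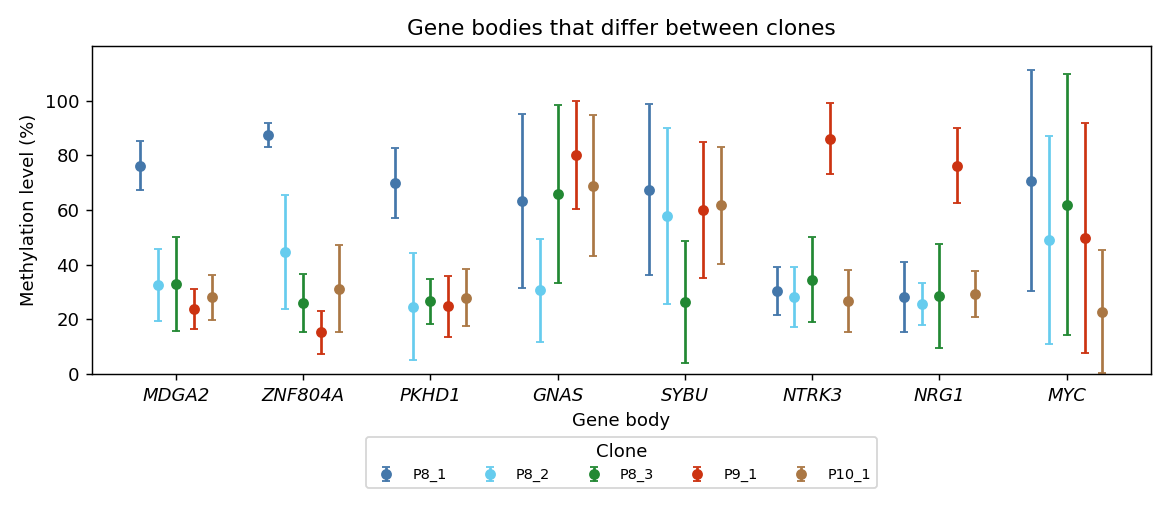
Methylation level (y axis, percent) of 8 gene bodies (x axis) in each clone, as the mean and SD over cells. NTRK3 is at 86.1% in P9_1 and MDGA2 at 76.2% in P8_1, while the other clones are at most at 34.6% and 32.9%.

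Gene ends differed between clones in 86 cases in odd- and in even-numbered cells, of which 30 belonged to P8_1, 15 to P8_2, 12 to P8_3, 24 to P9_1 and 5 to P10_1. Simulated data without clone effects gave 58. If odd- and even-numbered cells were independent, 15.9, 9.74, 8.22, 7.28 and 2.88 would be expected in these clones, in the same order. Of gene ends chosen in odd- or in even-numbered cells, 49.2% and 43.3% kept their sign in the remaining cells, against 40.7% in simulated data without clone effects. The shares were 61.3% and 60.2% for 100-kb windows (simulated 48.5%) and 61.0% and 57.7% for gene bodies (simulated 46.9%). All 24 P9_1 gene ends were higher there, as were 28 of 30 in P8_1, 15 of 15 in P8_2 and 11 of 12 in P8_3, against 2 of 5 in P10_1. APC, a tumour suppressor of the Wnt pathway (chromosome 5, 112706498 to 112708498), was at 86.9% ± 20.2 in 11 P9_1 cells and at most 3.16% elsewhere, with 6.88 times the coverage. VHL, a tumour suppressor of the hypoxia pathway, was at 88.6% ± 17.5 in 12 P9_1 cells and at most 46.7% elsewhere, with 4.11 times the coverage. SDHA and SDHB, subunits of succinate dehydrogenase, were at 82.4% ± 31.7 and 89.4% ± 29.9, and BRCA1, of DNA repair, was at 80.2% ± 28.4, with 1.97, 2.13 and 2.44 times the coverage. EPCAM, an epithelial adhesion gene, was at 92.1% ± 18.6 with 1.67 times the coverage. TWIST1, a mesenchymal transcription factor that is not on the panel list, was at 90.4% ± 21.9 in 8 P9_1 cells and at most 22.2% elsewhere, with 0.602 times the coverage. Of the 24 gene ends 10 were on the panel list, and none of those of the other clones was. That list was written after hints of extra coverage of tumour genes in P9_1 had been seen, so this count is not independent evidence.

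In the other clones the named gene ends rested on 2 to 5 cells, and the specific gene ends of a clone had a median of 0.466, 0.302, 0.537 and 0.380 times the coverage of the remaining clones in P8_1, P8_2, P8_3 and P10_1. The counts of these clones lay nearer to those expected from independence than the count of P9_1 did. The gene ends named below may therefore include chance cases. In P8_1, SNRNP25, of the minor spliceosome, was at 100% in 2 cells and at most 23.1% elsewhere, ANAPC15, of the anaphase-promoting complex, at 94.4% ± 4.90 in 3 cells and at most 24.9% elsewhere, and AMIGO3 at 4.39% ± 7.60 in 3 cells and at least 78.1% elsewhere. In P8_2, DCAF10 was at 100%, ARHGAP9 at 94.4% ± 9.62 and DAPK2, a death-associated kinase, at 87.5% ± 3.54. In P8_3, DOLK, for dolichol kinase, was at 97.5% ± 3.54, the mitochondrial ribosomal gene MRPS28 at 100% and the co-chaperone gene BAG3 at 100%. In P10_1, HSPA1B, a heat shock gene, was at 8.87% ± 9.89 in 4 cells and at least 75.2% in 11 to 12 cells of each other clone, ZNF853 at 76.2% ± 25.6 in 5 cells and the activin receptor gene ACVR1C at 51.7% ± 36.1 in 3 cells.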

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

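The tests on rows of wells, on reads of panel genes and on the over-covered bins were chosen after the results were seen. Values of the 5 clones were searched for a clone far from the others, its gap exceeding 0.71 of the range. Of 48 sets of clone values 4 had such a clone, against 2.4 expected by chance, and all 4 concerned P9_1. Panel genes held 1.43% of the covered positions in P9_1 and between 0.439% and 0.458% in the other clones. Their methylation level was 83.6% in P9_1 and between 53.4% and 57.9% in the other clones. The median gene-end level was 55.8% in P9_1 for tumour suppressor genes and 76.4% for epithelial and mesenchymal genes. The list of panel genes was written after hints of the first of these patterns and shares genes with the tumour suppressor list, so those sets are not independent. The count of 4 can therefore not be read as an excess over the 2.4 expected.

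On the mitochondrial genome, which no comparison used, read counts summed over positions came to 1928758. Of these 30.1% were methylated, between 18.3% and 53.9% by cell. No cause was tested.

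Cells of the same clone resembled each other more than the mean of the other clones in all 5 clones, or in 4 of 5 with 5-kb windows, although P10_1 cells were nearer to P9_1 (0.549) than to each other (0.536), and several technical sources were tested as the whole cause. After thinning all cells to 1 depth 0.736 of the contrast was left, and without the 10 chromosomes of varying coverage 1.01 of it. Neighbouring rows of wells of the P8 clones differed by at least 0.0392 in centred r between same and different clones. This test takes the P8 clones to lie on 1 plate, which is not given. It cannot detect an effect of rows handled in the pairs that hold a clone. Against reads passing between libraries, the excess of shared positions was 1.03 times as high within as between clones, though P9_1 pairs had a median excess of 1.27 and 18 of 66 exceeded every pair of different clones. At positions covered in 1 cell of a pair 0.730 of the contrast was left in P9_1 and 0.638 of the mean contrast of the 4 other clones, in which P8_2 weighs most, with 53.6% left in P8_1, 76.5% in P8_2, 61.4% in P8_3 and 50.8% in P10_1, so for P8_1 and P10_1 taken alone this test lies near the 50% set in advance and excludes nothing. Reads present in both libraries of a pair are thus excluded as the whole cause over the clones, not as part of it. Reads that reached both libraries from another cell or a common source can lie at different positions, so this test cannot exclude them.

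Unconverted DNA of a tumour gene panel is a candidate source of the extra coverage in P9_1. Without the over-covered bins 0.847 of the uncentred contrast of P9_1 was left, and such reads outside those bins were not excluded. With centring on the 3 clones outside a pair, the contrast of P9_1 fell from 0.107 to 0.0662 without those bins. With all bins, that centred contrast was 0.067 in the P9_1 cell of lowest panel share (A1, 0.652%). It was 0.163 in the cell of highest share (B5, 3.44%), so part of the contrast may stem from such reads. For the P9_1 gene ends this source stays open, with a median relative coverage of 1.997, 12 of 24 above 2 and 21 of 24 kept without the over-covered bins, which need over 3 times the coverage, and the batch of each clone cannot be told apart from the clone.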

How the results depend on the processing

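Alternatives that used positions of 1 cell, over-covered bins, varying chromosomes, cells of uneven coverage, the most similar cell with centring on the 5 clones or centring on the 3 clones outside a pair were chosen after seeing the data. Of 77 alternatives of values without a test, 34 kept a count within 1.5 times or another value within 1 SD over clones and 43 moved it further. In 73 alternatives of permutation tests, where p cannot fall under 0.05, nothing but the direction could change, and 0 reversed it. Some of the 73 were centred on the 5 clones, the coverage profiles among them, and there the direction was not free to change. The 0 is therefore no measure of stability for those. Apart from centring on the 5 clones, whose sign is fixed by construction, the contrast stayed above 0 in all 22 alternatives, from 0.0193 to 0.148, and from 0.0270 to 0.0356 when 1 clone was left out, where p cannot go below 0.125. Among the P8 clones it lay between 0.0204 and 0.158, the difference of the P8 pairs between −0.0228 and −0.00285 without that centring, and the coverage contrast between 0.0499 and 0.143. All coverage profiles were relative to the mean of the 5 clones, and their contrast without clone effects was not simulated. The p-values therefore say nothing on stability. No paired analysis was possible because replicate numbers only name cells and pair nothing across clones.

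Assignment varied with the setting, with 57 cells correct with 100-bp windows, 16 with 5-kb windows, 41 with at least 2 reads per position, 52 after thinning, 46 with a shrinkage weight of 5 calls, and 33 of 35 with the P8 clones as choices. The nearest clone by mean r was right for 47 cells, also 47 without over-covered bins and 41 at positions covered in 1 cell of a pair, and the most similar cell for 45. Centring on the 5 clones gave 58, as it did in simulated data without clone effects. The difference between neighbouring rows became 0.0452 with centring on the 3 other clones. The methylation level was 64.8% as a mean of position rates, 57.2% with at least 2 reads and 66.6% in 100-kb windows covered in every cell.

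Clone-specific 100-kb windows numbered 30 with a threshold 10 points higher, 647 with one 10 points lower, 47 with double the minimum of positions, 22 with at least 2 reads and 86 without the cells of uneven coverage. Gene ends numbered 42, 198 and 32 with the higher threshold, the lower one and at least 2 reads, and gene bodies 11, 192 and 21. With at least 2 reads, fewer regions met the minimum of cells. These were 4351 windows, 2377 gene ends and 2072 gene bodies, against 14568, 5351 and 5136, so these counts are not set against equal numbers of regions. With 500 bp around gene ends, medians were 28.8% for imprinted, 12.1% for HOX, 16.7% for developmental, 16.1% for kidney, 50.7% for blood cell, 39.9% for epithelial and mesenchymal, 15.0% for DNA methylation, 31.2% for protocadherin, 10.3% for zinc finger and 68.9% for olfactory receptor genes, and the pluripotency list gave no value. With reads pooled per clone they were 12.3% for housekeeping, 12.8% for HOX, 18.1% for developmental, 19.9% for neuronal, 29.1% for epithelial and mesenchymal, 13.7% for DNA methylation and 18.0% for zinc finger genes. The causes were not tested. At this depth odd- and even-numbered cells alike recovered 27.0% of simulated shifts in gene ends, against 87.0% in windows and 93.0% in gene bodies, which also differ in threshold and minimum.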

Other observations

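The tests of a common origin and of incomplete conversion were chosen after the results were seen. Some list members not described above, chosen after their values were seen, sat at either extreme of gene-end methylation. Among germline genes BOLL, an RNA-binding protein of meiosis, was at 94.7% ± 2.82 (SD, n = 5 clones). Among imprinted genes NDN was at 79.6% ± 4.69 and ZDBF2 at 5.34% ± 7.44. HOXB1, a hindbrain patterning gene, was at 93.7% ± 8.11, SFRP2, a secreted Wnt inhibitor, at 92.9% ± 9.28, and LEFTY1, a NODAL inhibitor, at 90.0% ± 3.195.

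P10_1 cells A1 and A4 had methylation levels of 64.6% and 65.4%, against 56.3% to 59.9% in the other 9 cells of the clone. A4 was also the deepest of all cells. Reads of A4 in the library of A1 did not account for both, since the excess of shared positions of A1 with A4 was 1.13 times the highest of A4 with another cell of the clone, under the 1.5 times set before the test. Coverage leaning to CpG-dense or CpG-poor sequence was argued against, as 2 of the 2 cells stayed above the other 9 with density strata weighed equally. Incomplete bisulfite conversion or reads of unconverted DNA may contribute, since at housekeeping gene ends 1 of these cells, A1 with 28.8%, lay above the other 9 (4.28% to 23.05%), and A4 with 19.1% did not. No biological explanation was tested.

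P9_1 and P10_1 were the most similar pair of clones with all positions and no centring, and a hypothesis is that both share a common origin. Their coverage profiles, relative to the mean of the 5 clones, had rank 1 of 10 pairs, in a test chosen after the similarity was seen. A common origin of the 2 clones would give this rank. The rank was not computed without that centring or at equal depth, so it is weak support. Shared copy number of a few chromosomes was argued against, since the pair kept rank 1 without the varying chromosomes. The rule set in advance for depth of the libraries, a rank over 1 in centred similarity after thinning, was met. The pair had rank 3 in each of 5 draws with rates centred on the 3 clones outside the pair, against rank 1 with that centring and no thinning. Without centring it had rank 1 or 2 over these draws. Depth may thus account for the rank but is not settled as its cause. The rule set in advance for reads passing between libraries, a rank over 1, was likewise met. At positions covered in 1 cell of a pair the rank was 2, by a small gap (0.491 against 0.492). The median excess of shared positions of P9_1 and P10_1, 1.12, was among the lower ones of the 10 pairs of clones (1.11 to 1.17). Such reads therefore also stay open.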
